A study of Mus musculus with 12 samples.

How the data were processed

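The series holds 12 RNA sequencing libraries of G1E-ER4 cells in 4 groups of 3, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, cells were treated with 10 µM TMG, 1 µM E2 or both for 30 h, and stranded poly(A) libraries were sequenced as read pairs. The labels name the cell type as embryonic stem cell; the line is described here as in the sample descriptions. Per the submitters' processing notes and the series design text, reads were checked with FastQC 0.11.2, aligned to GRCm38 and quantified with RSEM 1.2.22 (Bowtie2 is also named), and compared by the authors with edgeR 3.14.0 in R 3.2.2. Per the file headers, each deposited file gives expected counts, TPM and FPKM for 32699 genes. The deposited expected counts are RSEM estimates that need not be whole, since reads that match several genes are divided among them. The deposited TPM and FPKM values are scaled by the authors for transcript length and depth, and were not used for any test. Whether RSEM was run with a strand setting is not given in the sources used here, so that genes overlapping on opposite strands, such as Il1b and Il1bos, are uncertain.

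Expected counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. As in the series design text, genes with a CPM over 10 in at least 2 of the 12 libraries were kept (8273) and libraries were scaled by TMM. All 12 libraries entered a single quasi-likelihood fit with a mean per group, 5 comparisons were tested, and p-values were adjusted by the Benjamini-Hochberg method over the genes kept, with 0.05 as the threshold. The SE of a log2 fold change was computed from the F statistic. CPM values in the text are scaled by TMM, except the highest library values of cell type markers, which are scaled by library size alone. Of 26 gene lists fixed before the data were examined, 22 had at least 3 members kept and were tested with camera of limma 3.58.1 (inter-gene correlation preset at 0.01, adjusted over the lists); 4, 1, 0, 4 and 1 lists were called with an estimated correlation, in the order E2 vs Ctrl, TMG vs Ctrl, TMG_E2 vs E2, TMG_E2 vs TMG and interaction. The megakaryocyte and granulocyte lists had 1 member kept each (Nbeal2 and Coro1a), and the lymphoid and embryonic stem cell lists none. Some list genes, such as Hba-a1 and Hbb-bt, are not analysed here.

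The genes named in the text were chosen by a rule fixed before the data were examined. For E2 vs Ctrl, TMG vs Ctrl and TMG_E2 vs E2 it takes the 6 highest and 6 lowest fold changes among called genes whose groups did not overlap, the called member with the smallest p of each list (and the next where camera calls the list), and always Gata1, Gata2, Klf1, Ogt and Oga. For the other comparisons it takes the 5 highest and lowest and the same fixed genes, with no overlap condition for the interaction. The interaction is also given for genes named in other comparisons. Most genes of the last part were picked outside this rule, after their values were seen. Results of some genes are not reported here, though the counts of named genes include them. Positions come from RefSeq on GRCm38, the build of the files.

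No pair of replicates agreed within sampling noise (chi-square per degree of freedom 2.41 to 13.1, highest between TMG_E2 libraries). Whether replicate numbers pair the libraries was checked from the correlation of deviations from the group means. Same-numbered libraries correlated above 0.1 for each number in E2 vs Ctrl (0.108, 0.278 and 0.112), TMG_E2 vs E2 (0.285, 0.182 and 0.201) and TMG_E2 vs TMG (0.525, 0.149 and 0.412), so the numbers were taken to pair them there. The pairing comes from the data, as the labels state no shared day. The main fit holds no block for it, as the series design text states none, so the main p-values leave the pairing out. The block was run as an alternative.

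The depth of 17589400 to 23178700 counts puts 3 counts at 0.133 to 0.180 CPM in a library. The test was tried on a single simulated set of counts per comparison, over 8273 genes with 67, 67 and 66 changed 1.2-fold, 1.5-fold and 2-fold. Library sizes were the real ones, while each gene had its mean over all libraries and a spread shared by all groups. It recovered 64.2%, 98.5% and 100% of them for E2 vs Ctrl and 62.7%, 100% and 100% for TMG vs Ctrl. It recovered 71.6%, 98.5% and 100% for TMG_E2 vs E2, 64.2%, 95.5% and 100% for TMG_E2 vs TMG, and 46.3%, 98.5% and 100% for the interaction. Genes that were not changed made up 1.13%, 4.37%, 6.74%, 6.49% and 2.98% of the calls, where 5% was aimed at. As each value comes from a single set, the differences between comparisons cannot be told from chance. The larger spread of the real TMG_E2 replicates was not simulated, so the share of false calls there was not measured. In each comparison both lists changed 1.2-fold were recovered, with 0 other lists called. Simulated genes vary independently and real ones do not, so this does not measure false list calls in the real data. Other splits of the real libraries called up to 10 lists for E2 vs Ctrl, 8 for TMG vs Ctrl, 8 for TMG_E2 vs E2 and 9 for TMG_E2 vs TMG.

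Alternatives were no filter, edgeR's own filter, other scalings, unrounded counts, the replicate number as a block, only the groups compared, DESeq2 1.42.0, limma-voom, each library left out, and for lists an estimated correlation and fry. A correction for transcript length and GC content was added after seeing the data. Correlations of comparisons that share libraries are given beside values from 20 simulated sets of unchanged groups. Figures were drawn with matplotlib 3.10.9.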

Results

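Gene expression was measured by RNA sequencing in G1E-ER4 cells, a mouse erythroid progenitor line. The line carries the transcription factor GATA-1 fused to the estrogen receptor, so that β-estradiol (E2) starts red cell differentiation. The labels give 4 groups of 3 libraries: untreated cells (Ctrl), cells given 10 µM Thiamet-G (TMG), cells given 1 µM E2, and cells given both (TMG_E2), with treatments of 30 h. TMG blocks OGA, the enzyme that removes O-GlcNAc from proteins. The libraries held 17589400 to 23178700 expected counts each, and 8273 of 32699 genes passed the expression filter. The first principal component took 94.8% of the variance and separated the libraries with E2 from those without it. Embryonic stem cell and lymphoid markers were low, with highest library values of 0.272 CPM (Nanog) and 1.25 CPM (Lck), and no gene of these lists passed the filter. Some markers of other blood cells were not low: the highest library values were 83.7 CPM for Nbeal2 (megakaryocyte), 23.7 CPM for Coro1a (granulocyte) and 72.3 CPM for Il1rl1 (mast cell). Levels are CPM ± SD with n = 3 per group, changes are log2 fold changes ± SE with edgeR adjusted p-values, and positions are on GRCm38. Nothing states that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

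The comparison of E2 with Ctrl asked what E2 changed without TMG. The groups hold no cells that lack the fusion and were given E2, so other effects of E2 cannot be told from differentiation. Genes of hemoglobin production and of the red cell membrane rose. Hbb-bs, an adult beta globin gene (chromosome 7, 103826523 to 103827928), went from 19.0 ± 1.94 to 19926 ± 1218 CPM (log2 10.03 ± 0.10, adjusted p = 3.01e-21). Alas2, the first enzyme of erythroid heme synthesis (chromosome X, 150547417 to 150570622), went from 2.17 ± 0.424 to 657 ± 17.2 CPM (log2 8.23 ± 0.07). Slc4a1, the band 3 anion exchanger (chromosome 11, 102348820 to 102365281), went from 1.17 ± 0.131 to 2226 ± 108 CPM (log2 10.88 ± 0.10). Gata1 rose (log2 1.85 ± 0.04), as did Klf1, an erythroid transcription factor gene (log2 1.55 ± 0.05). Here and below, Gata1 values may include reads of the introduced GATA-1 fusion, which were not told apart. Gata2, which GATA-1 is known to repress, fell from 524 ± 33.2 to 20.7 ± 1.75 CPM (log2 -4.66 ± 0.07). Tmem184a had 0 counts in the 3 Ctrl libraries together and 2648 with E2, at least 970.4-fold higher against a floor of 3 counts over the group.

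All 4 tested globin genes rose with E2 (median log2 6.49, camera adjusted p = 9.69e-13), and the list had adjusted p = 0.00101 with an estimated correlation. All 12 heme synthesis genes rose (median 2.13, adjusted p = 6.13e-34; adjusted p = 0.000968 with an estimated correlation), among them Abcb10 (log2 4.04 ± 0.05). All 16 tested red cell membrane and cytoskeleton genes rose (median 2.54, adjusted p = 4.42e-33; adjusted p = 0.000968 with an estimated correlation). Of 9 tested progenitor genes that GATA-1 represses, 7 fell and 1 rose (median -2.34, adjusted p = 1.04e-08). That list had adjusted p = 0.00684 with an estimated correlation, and Myb was among the genes that fell (log2 -2.48 ± 0.04). All 16 ribosome biogenesis genes fell (median -1.10, adjusted p = 1.04e-08), for example Nop2 (log2 -1.47 ± 0.05), and that list had adjusted p = 0.134 with an estimated correlation. In E2 vs Ctrl, each list had the same counts adjusted over the list alone. Some members, such as Hbb-b2, Hbb-bh1, Alas2 and Slc4a1, passed the expression filter only through libraries with E2, which favours a rise.

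Of 13 lysosome genes 11 rose and 1 fell with E2 (adjusted p = 0.000146), with Ctsb at log2 3.04 ± 0.04. The list had adjusted p = 0.134 with an estimated correlation. Of 15 erythroid transcription factor genes 11 rose and 2 fell (adjusted p = 0.000883), with Lmo2 at log2 1.79 ± 0.04. That list had adjusted p = 0.212 with an estimated correlation. Of 9 genes of cell cycle inhibition and exit 8 rose (adjusted p = 0.00124; adjusted p = 0.103 with an estimated correlation), with Cdkn1a at log2 1.17 ± 0.05. Of 15 autophagy and mitochondrial clearance genes 11 rose and 3 fell (adjusted p = 0.00863; adjusted p = 0.134 with an estimated correlation). Of 16 oxidative stress genes 7 rose and 5 fell (adjusted p = 0.0123; adjusted p = 0.171 with an estimated correlation), a call that also ended with the length and GC offset (adjusted p = 0.174). Of 19 cholesterol genes 16 rose and 2 fell (adjusted p = 0.0262; adjusted p = 0.657 with an estimated correlation), with Idi1 at log2 1.33 ± 0.05.

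The few markers of other blood cells that passed the filter fell with E2. All 3 tested mast cell markers fell (adjusted p = 0.000883; adjusted p = 0.134 with an estimated correlation). They and Coro1a passed the expression filter only through libraries without E2, so the list test gives no independent support for a fall. Il1rl1 went from 56.6 ± 2.36 to 0.429 ± 0.343 CPM and Ms4a2 from 14.7 ± 4.19 to 0.0804 ± 0.0724 CPM. Cpa3 went from 991 counts to 1 count, a ratio of 901 with a 95% interval of 161 to 35637 that covers counting error only. The megakaryocyte and granulocyte lists had 1 gene each past the filter and were not tested as lists: Nbeal2 fell (log2 -1.59 ± 0.09), as did Coro1a (log2 -3.40 ± 0.15).

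The lists not called in E2 vs Ctrl held genes of either direction. Iron handling had 6 of 13 genes higher and 5 lower (adjusted p = 0.0513; adjusted p = 0.0258 with the replicate block, 0.0398 without E2 replicate 1 and 0.0392 without E2 replicate 3), with Slc25a37, a mitochondrial iron importer, at log2 4.53 ± 0.04. G2 and mitosis had 13 of 18 higher and 3 lower (adjusted p = 0.0526; 0.0472 without Ctrl replicate 2 and 0.0405 without E2 replicate 3), and the NuRD complex 2 of 12 higher and 8 lower (adjusted p = 0.0871). S phase had 9 of 20 higher and 6 lower, glycolysis 4 of 16 and 7, JAK-STAT signalling 6 of 12 and 6, and the interferon response 3 of 4 and 1 (adjusted p = 0.674 for each). Apoptosis had 7 of 14 higher and 5 lower (adjusted p = 0.674), with a median of 0.11, a mean of -0.07 and a test direction of lower. The unfolded protein response had 6 of 15 higher and 6 lower (adjusted p = 0.996). O-GlcNAc cycling had 5 of 11 higher and 5 lower (adjusted p = 0.985). In it Oga (listed as Mgea5, chromosome 19, 45750255 to 45783644) rose by log2 0.55 ± 0.04 and Ogt by 0.49 ± 0.04, while Gfpt1, the entry enzyme of the hexosamine pathway, fell from 413 ± 5.46 to 93.2 ± 1.78 CPM.

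Between E2 and Ctrl 6838 of 8273 genes were called, 3432 higher and 3406 lower, of which 717 and 718 changed 2-fold or more. With library size alone as the scaling, 2871 were higher and 3952 lower, and 26 called genes changed sign. The lower genes were also more with no filter (4270 and 4381) and with the length and GC offset (3461 and 3513).

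**Figure D1:**
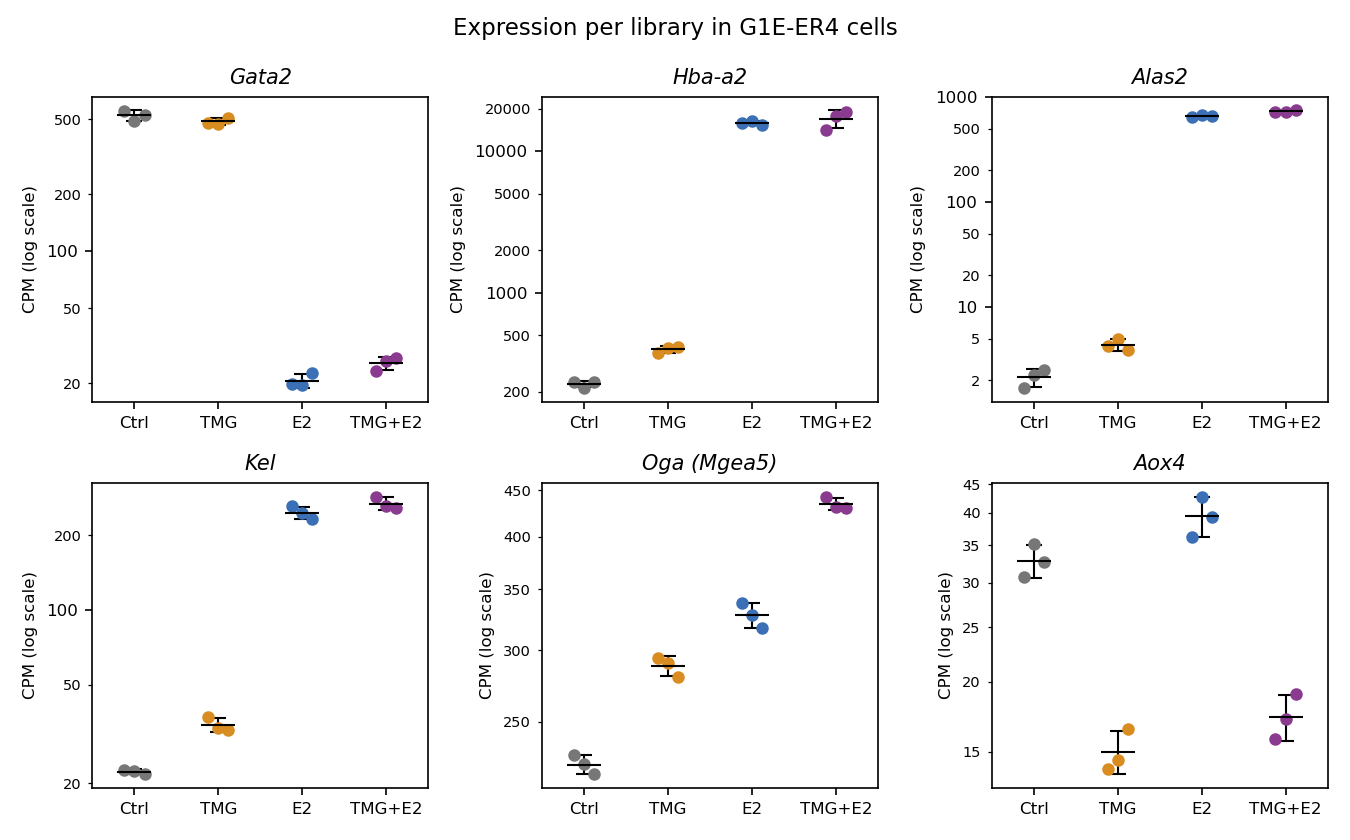
Expression of 6 genes in each of the 12 libraries, as CPM on a log axis, by treatment group; points are libraries, the long bar is the group mean and the error bars are 1 SD (n = 3). Hba-a2 went from 227 CPM in Ctrl to 399.6 CPM with TMG and 15847 CPM with E2, and Oga (Mgea5) was higher with TMG without E2 (288 against 224 CPM) and with it (435 against 328 CPM).

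The comparison of TMG with Ctrl asked what blocking O-GlcNAc removal did in uninduced cells. Oga, the gene of the enzyme that TMG inhibits, rose from 224 ± 5.34 to 288 ± 6.98 CPM (log2 0.36 ± 0.04, adjusted p = 1.73e-05). Ogt, the gene of the enzyme that adds O-GlcNAc, was at log2 0.08 ± 0.04 (adjusted p = 0.338). Some globin and heme genes rose: Hba-a2 went from 227 ± 12.3 to 399.6 ± 21.9 CPM (log2 0.82 ± 0.08, adjusted p = 2.00e-05) and Alas2 from 2.17 ± 0.424 to 4.38 ± 0.558 CPM (log2 1.01 ± 0.14, adjusted p = 0.000488). Hbb-bs rose by log2 0.71 ± 0.10 (adjusted p = 0.000446). Aox4, an aldehyde oxidase gene (chromosome 1, 58210397 to 58268600), fell from 32.9 ± 2.23 to 15.0 ± 1.31 CPM (log2 -1.14 ± 0.08, adjusted p = 9.84e-07). Fndc5 had the highest fold change among called genes whose groups did not overlap (log2 1.43 ± 0.17).

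Of the 4 tested globin genes 2 rose with TMG, and 2 adjusted over the list alone (median 0.62, camera adjusted p = 1.27e-09). Hbb-b2 went from 2.77 to 3.95 CPM and Hbb-bh1 from 0.123 to 0.174 CPM, where 3 counts in a library are 0.133 to 0.180 CPM. Both passed the expression filter only through the libraries with E2. The globin list had adjusted p = 0.00351 with an estimated correlation. Globin genes are close copies, so the division of reads among them is uncertain. Of 12 heme synthesis genes 2 rose (9 rose and 1 fell adjusted over the list alone; adjusted p = 3.47e-06), and the list had adjusted p = 0.108 with an estimated correlation. Of 16 red cell membrane genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.000283), and the list had adjusted p = 0.141 with an estimated correlation. Kel, a blood group protein gene, went from 22.3 ± 0.443 to 34.4 ± 2.19 CPM, and Add2, an adducin gene, fell from 188 ± 8.60 to 146 ± 4.73 CPM. Of 19 cholesterol genes 6 rose (8 adjusted over the list alone; adjusted p = 1.03e-06), among them Idi1 (log2 0.27 ± 0.05) and Fdps (log2 0.26 ± 0.05). That list had adjusted p = 0.294 with an estimated correlation and 0.0606 with fry.

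Genes also rose with TMG in 3 other lists called higher. Of 4 interferon response genes 1 rose, Ifi35 (log2 0.28 ± 0.05), and 3 adjusted over the list alone (adjusted p = 0.00390; adjusted p = 0.108 with an estimated correlation). Of 12 JAK-STAT genes 3 rose, with Socs2 at log2 0.25 ± 0.05, and 3 rose and 1 fell adjusted over the list alone (adjusted p = 0.00707; adjusted p = 0.188 with an estimated correlation). Of 9 cell cycle inhibitor genes 1 rose, Cdkn1a (log2 0.31 ± 0.05), and 3 adjusted over the list alone (adjusted p = 0.00939; adjusted p = 0.187 with an estimated correlation). The last call ended without TMG replicate 2 (adjusted p = 0.0583). Gata1 was at log2 0.14 ± 0.04 (adjusted p = 0.0644, but 0.0358 with only the groups compared, 0.0441 with DESeq2 and 0.0257 with the length and GC offset). Klf1 was at 0.16 ± 0.06 (adjusted p = 0.126, but 0.0400 with only the groups compared and 0.00886 with the length and GC offset). Gata2 was at -0.11 ± 0.05 (adjusted p = 0.286). The erythroid transcription factor list was not called (median -0.0047, mean 0.03, adjusted p = 0.568), nor was the unfolded protein response (median 0.01, mean -5.8e-05, adjusted p = 0.827). The progenitor list had 2 of 9 genes lower (3 adjusted over the list alone; adjusted p = 0.0524, but 0.0216 with filterByExpr, 0.00930 without Ctrl replicate 2 and 0.0333 without TMG replicate 3). Mast cell markers had 2 of 3 genes lower (2 lower and 1 higher adjusted over the list alone; median -0.64), and that list was not called (adjusted p = 0.547). The other lists not called in TMG vs Ctrl were O-GlcNAc cycling (adjusted p = 0.0901), apoptosis (0.278), oxidative stress and lysosome (0.280 each), ribosome biogenesis (0.285), iron handling, autophagy and G2 and mitosis (0.310 each), S phase (0.415), glycolysis (0.702) and the NuRD complex (0.827).

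TMG changed 426 genes in uninduced cells, 249 higher and 177 lower, with a median fold of 1.20 among them. With library size alone as the scaling, 179 were higher and 232 lower. The count was 196 to 257 when any 1 of the 6 libraries was left out, and 768 when only these libraries were fitted. Lars2 (log2 -1.08 ± 0.26) and AK155692 (log2 -1.48 ± 0.30) were lower, but Ctrl replicate 2 had 356 and 303 CPM of them, against 118 to 159 and 89.0 to 126 CPM in the other Ctrl libraries.

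The comparison of TMG_E2 with E2 asked what blocking O-GlcNAc removal did to differentiating cells. Oga rose from 328 ± 10.4 to 435 ± 6.99 CPM (log2 0.41 ± 0.03, adjusted p = 8.05e-06). Aox4 fell from 39.5 ± 3.24 to 17.3 ± 1.61 CPM (log2 -1.20 ± 0.08, adjusted p = 5.75e-07), and was the only one of the 1055 called genes with a change of 2-fold or more. Of the genes tested, 11 of 19 for cholesterol, 6 of 13 for lysosomes and 5 of 16 for oxidative stress rose, and 9 of 16 for ribosome biogenesis fell. The calls of these lists were lost with an estimated correlation (adjusted p = 0.204, 0.109, 0.102 and 0.247). Slc4a1 fell from 2226 ± 108 to 1822 ± 147 CPM (log2 -0.29 ± 0.05, adjusted p = 0.00144). Gata1 was at log2 0.01 ± 0.04 (adjusted p = 0.892) and Klf1 at -0.03 ± 0.05 (adjusted p = 0.797). Ogt was at log2 0.13 ± 0.04 (adjusted p = 0.0604). It was called with the replicate block (adjusted p = 0.0146), no filter (0.0481), RLE size factors (0.0431), DESeq2 (0.0250), the length and GC offset (0.0287) and without TMG_E2 replicate 3 (0.0201).

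Of 19 cholesterol genes 11 rose with TMG in E2-treated cells (13 adjusted over the list alone; median 0.18, adjusted p = 1.24e-09), and the list had adjusted p = 0.204 with an estimated correlation. Hmgcs1, which makes the precursor of mevalonate, went from 569.6 ± 32.4 to 753 ± 69.2 CPM. Of 16 ribosome biogenesis genes 9 fell (11 fell and 1 rose adjusted over the list alone; median -0.16, adjusted p = 2.66e-06). That list had adjusted p = 0.247 with an estimated correlation. Polr1b, a subunit of RNA polymerase I, was at log2 -0.36 ± 0.06 and Nop2 at -0.31 ± 0.05. Of 13 lysosome genes 6 rose (8 adjusted over the list alone; adjusted p = 5.70e-06; adjusted p = 0.109 with an estimated correlation), with Laptm5 at log2 0.37 ± 0.04 and Lamp2 at 0.27 ± 0.04. Of 16 oxidative stress genes 5 rose (7 adjusted over the list alone; adjusted p = 6.19e-06; adjusted p = 0.102 with an estimated correlation), with Nqo1 at log2 0.38 ± 0.04 and Srxn1 at 0.36 ± 0.04.

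Smaller numbers of genes rose in 5 other lists called higher. Of 15 autophagy genes 2 rose (2 adjusted over the list alone; adjusted p = 0.00729; adjusted p = 0.109 with an estimated correlation), with Map1lc3b at log2 0.24 ± 0.04. Of 11 O-GlcNAc genes 2 rose (4 adjusted over the list alone; adjusted p = 0.00969; adjusted p = 0.109 with an estimated correlation), Oga and Gnpda1 (log2 0.24 ± 0.04), a call that ended with the length and GC offset (adjusted p = 0.170). Of 14 apoptosis genes 2 rose (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.0223), and the list had adjusted p = 0.109 with an estimated correlation. Of 4 interferon genes 2 rose (2 adjusted over the list alone; adjusted p = 0.0223; adjusted p = 0.140 with an estimated correlation), a call that ended without TMG_E2 replicate 1 (adjusted p = 0.0508), without E2 replicate 3 (0.0592) or with filterByExpr (0.0813). Of 12 JAK-STAT genes 3 rose (3 adjusted over the list alone; adjusted p = 0.0388; adjusted p = 0.265 with an estimated correlation), a call that ended without E2 replicate 1 (adjusted p = 0.0593), without TMG_E2 replicate 2 (0.0554) or without TMG_E2 replicate 3 (0.163).

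The erythroid lists were not called with TMG in E2-treated cells. Of 4 globin genes 1 rose, Hbb-bh1 (log2 0.48 ± 0.09; list adjusted p = 0.113, and 0.0174 without E2 replicate 1), of 12 heme genes 1 rose (list adjusted p = 0.722), and of 16 membrane genes 2 fell (list adjusted p = 0.236), with the same counts adjusted over the list alone. Gata2 rose from 20.7 ± 1.75 to 25.6 ± 2.03 CPM (log2 0.30 ± 0.08, adjusted p = 0.0223). The Gata2 call ended without E2 replicate 1 (adjusted p = 0.0701), E2 replicate 2 (0.0882), TMG_E2 replicate 2 (0.0578) or TMG_E2 replicate 3 (0.0691), or with only the groups compared (0.0536). Coro1a, the only granulocyte marker past the filter, rose from 1.83 ± 0.230 to 2.96 ± 0.470 CPM (log2 0.67 ± 0.20, adjusted p = 0.0356). The Coro1a call ended with only the groups compared (adjusted p = 0.0538), with limma-voom (0.0758), and without E2 replicate 1 (0.0598), 2 (0.0633) or 3 (0.137) or TMG_E2 replicate 2 (0.0934) or 3 (0.0904).

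The other lists not called in TMG_E2 vs E2 were G2 and mitosis (adjusted p = 0.0877, but 0.0497 with filterByExpr, 0.0166 without E2 replicate 1 and 0.0333 without TMG_E2 replicate 2), cell cycle inhibition (0.128), the unfolded protein response (0.372; 0.0434 without TMG_E2 replicate 1) and the NuRD complex (0.378). Erythroid transcription factors had adjusted p = 0.416, progenitor genes 0.562, glycolysis 0.606 (0.0446 without TMG_E2 replicate 3), iron handling 0.849, S phase 0.854 and mast cell markers 0.945.

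TMG changed 1055 genes in E2-treated cells, 464 higher and 591 lower, with a median fold of 1.18 among them. With library size alone as the scaling, 348 were higher and 764 lower, but with RLE size factors 566 were higher and 531 lower, and with DESeq2 523 and 470. The higher genes were also more without TMG_E2 replicate 1 (532 and 496) or TMG_E2 replicate 2 (494 and 473), so which direction held more genes was not settled. The count was 682 without E2 replicate 2, 656 without E2 replicate 3 and 539 when only these 6 libraries were fitted.

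**Figure D2:**
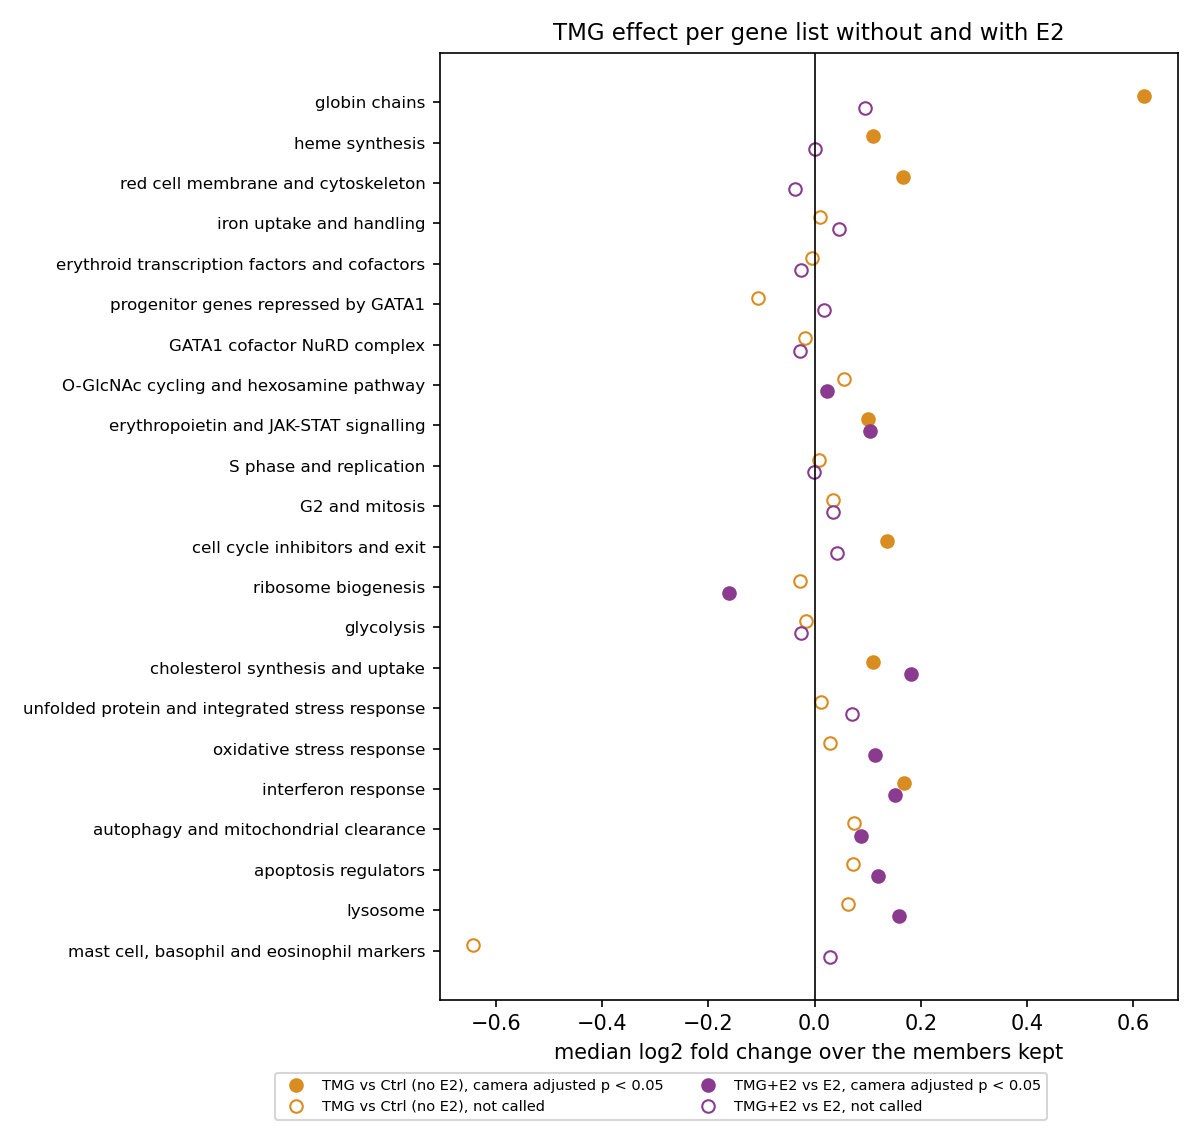
Median log2 fold change of the TMG effect for each of the 22 tested gene lists, without E2 (TMG against Ctrl) and with E2 (TMG_E2 against E2); filled points passed a camera adjusted p of 0.05 with the preset correlation. The globin list lies at 0.62 without E2 and 0.09 with it, and ribosome biogenesis at -0.03 and -0.16.

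The comparison of TMG_E2 with TMG asked what E2 changed where O-GlcNAc removal was blocked. All 4 globin genes (median 6.15, adjusted p = 4.69e-12), all 12 heme genes (median 1.95, adjusted p = 3.01e-31) and all 16 tested membrane genes rose (median 2.38, adjusted p = 4.70e-30). Each of these lists had adjusted p = 0.000773 with an estimated correlation. Gata1 rose by log2 1.72 ± 0.04 and Klf1 by 1.37 ± 0.05, and Gata2 fell (log2 -4.26 ± 0.07). Of 9 progenitor genes 6 fell and 2 rose (adjusted p = 8.16e-08; adjusted p = 0.0111 with an estimated correlation). All 16 ribosome biogenesis genes fell (median -1.26, adjusted p = 4.13e-10; adjusted p = 0.106 with an estimated correlation). G2 and mitosis genes were called higher (13 of 18 rose and 4 fell; adjusted p = 0.0399; adjusted p = 0.397 with an estimated correlation). These lists had the same counts adjusted over the list alone. Also called higher were lysosome (adjusted p = 1.48e-05; adjusted p = 0.0832 with an estimated correlation), autophagy (0.00315 and 0.0832 so estimated), cell cycle inhibition (0.00205 and 0.0832), oxidative stress (0.00266 and 0.0832), erythroid transcription factors (0.00205 and 0.262) and cholesterol (0.0112 and 0.580). Mast cell markers were called lower (0.00127 and 0.0866), though the tested members passed the filter only through libraries without E2. With the length and GC offset the oxidative stress list had adjusted p = 0.0532 and mast cell markers 0.0529. Iron handling had adjusted p = 0.0534, and adjusted p = 0.0267 with the replicate block, 0.0418 without TMG_E2 replicate 1 and 0.0310 without TMG_E2 replicate 3. The O-GlcNAc list (median -0.03, mean 0.08), the unfolded protein response (median -0.02, mean 0.31) and apoptosis (median 0.11, mean -0.04) were not called (adjusted p = 0.832, 0.832 and 0.763). Nor were the NuRD complex (0.0650, and 0.0474 with filterByExpr), JAK-STAT signalling (0.693), glycolysis (0.735), the interferon response (0.763) and S phase (0.789). In all 13 lists and 6841 genes were called, 3386 higher and 3455 lower. With library size alone as the scaling, 2893 were higher and 4005 lower, as that scaling moved the median of the genes kept to log2 -0.11. With RLE size factors 3440 were higher and 3398 lower, and with DESeq2 3384 and 3349.

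The E2 effects measured with and without TMG, which share no library, correlated across genes (Pearson r = 0.989, Spearman rho = 0.986; genes are not independent replicates). Of the genes called higher, 3210 were shared where independent lists give 1405, and of those called lower 3216 where they give 1422. The TMG effects measured with and without E2 also share no library and had r = 0.482 and rho = 0.507. In them 92 genes were called higher in both, where independent lists give 13.97, and 101 lower, where they give 12.6, against 3 and 1 in opposite directions. That r was 0.282 without TMG_E2 replicate 3 and 0.225 with edgeR's own filter, filterByExpr. Deviations of same-numbered TMG and TMG_E2 libraries from their group means correlated (0.525, 0.149 and 0.412). The TMG effects are thus not fully independent though they share no library, and the counts for independent lists leave this out. The TMG effect in E2-treated cells had r = 0.203 with the E2 effect measured from Ctrl (covariance 0.0295). Simulated unchanged groups that share the E2 libraries gave a covariance of -0.0031 (r = -0.504). With the E2 effect measured in TMG-treated cells the TMG effect had r = 0.287 (covariance 0.0414). Simulated unchanged groups gave a covariance of 0.0031 there (r = 0.499). The simulated groups hold no E2 effect, so their r cannot be set against the real r, and only the covariances compare. The r with the E2 effect measured from Ctrl was 0.0687 with filterByExpr.

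The interaction asked whether the TMG effect differed with and without E2, and 77 genes were called, 22 higher and 55 lower. The TMG fold was smaller in E2-treated than in uninduced cells for Hba-a2 (interaction log2 -0.71 ± 0.11, adjusted p = 0.00536) and Kel (-0.50 ± 0.08, adjusted p = 0.00918). It was smaller for Alas2 too (-0.86 ± 0.15, adjusted p = 0.00986), a call that ended without TMG replicate 2 (adjusted p = 0.0579). BB287469, 1 of a family of genes that share sequence, had the lowest interaction among called genes named here (log2 -1.21 ± 0.15, adjusted p = 0.000715). Aim1 was called the other way (0.67 ± 0.10, adjusted p = 0.00311). Oga had an interaction of 0.05 ± 0.05 (adjusted p = 0.822). Gata2 had 0.40 ± 0.10 (adjusted p = 0.0612), and was called with the replicate block (0.0164), no filter (0.00210), DESeq2 (0.00358), the length and GC offset (0.00542) and without TMG_E2 replicate 1 (0.0237).

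The globin list was called lower in the interaction (2 of 4 genes lower, 2 adjusted over the list alone, adjusted p = 8.82e-07, and adjusted p = 0.0115 with an estimated correlation). Of its genes, Hbb-bh1 lay near the level of 3 counts in a library without E2. The heme list was called lower (2 of 12 genes, 5 adjusted over the list alone; adjusted p = 1.35e-05; adjusted p = 0.0977 with an estimated correlation). So was the membrane list (2 of 16 genes lower and 1 higher, 8 and 1 adjusted over the list alone; adjusted p = 1.39e-05; adjusted p = 0.0977 with an estimated correlation). Ribosome biogenesis was called lower with 5 of 16 genes lower adjusted over the list alone (adjusted p = 2.50e-05; adjusted p = 0.345 with an estimated correlation). The lysosome list was called higher (adjusted p = 0.000372; adjusted p = 0.221 with an estimated correlation). Oxidative stress was called higher with 3 genes higher and 1 lower adjusted over the list alone (adjusted p = 0.00178; adjusted p = 0.154 with an estimated correlation), a call that ended without TMG_E2 replicate 3 (adjusted p = 0.0525). The progenitor list was called higher with 3 genes higher adjusted over the list alone (adjusted p = 0.0134; adjusted p = 0.186 with an estimated correlation), a call that ended without Ctrl replicate 1 (adjusted p = 0.0532) or E2 replicate 2 (0.102). Cholesterol and autophagy were not called (adjusted p = 0.0580 each), but were with filterByExpr (0.0389 each), with the replicate block (0.0180 and 0.0485) and when some single libraries were left out, for example cholesterol without TMG_E2 replicate 2 (0.000147) and autophagy without TMG_E2 replicate 1 (0.0177). The gene count was 18 to 161 over fits without 1 library, over 1.5 times away from 77 for each library but TMG_E2 replicate 1, and 40 with limma-voom.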

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

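The interaction test and its alternatives were planned, except the length and GC offset; the tests of the 3 patterns below and the counts over other splits were all chosen after the results they bear on had been seen.

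The TMG effect differed with and without E2, by the interaction test, for 77 genes. Among the named genes it was higher with E2 (interaction log2) for Fam198b (1.05), Fermt3 (0.96), Lgals9 (0.83), Aim1 (0.67), Ephx2 (0.67), Optn (0.48) and Add2 (0.25). It was lower for Abcb10 (-0.28), Kel (-0.50), Hbb-bs (-0.62), Mvb12a (-0.62), Hba-a2 (-0.71), Akr1e1 (-0.72), Alas2 (-0.86), Il1bos (-0.93), Asic4 (-1.02), Gm8300 (-1.03), Il1b (-1.09), Gm2016 (-1.21) and BB287469 (-1.21). Of these 20 genes, Hba-a2, Kel, Asic4, Il1bos, BB287469 and Aim1 kept their call under each alternative run, and the call of the other 14 ended under at least 1. For Alas2 it ended without TMG replicate 2 (adjusted p = 0.0579) and for Lgals9 without E2 replicate 2 (0.0680). For the rest it ended without 5 or more of the 12 libraries, with adjusted p-values up to 0.0851 for Hbb-bs, 0.0701 for Fermt3, 0.0639 for Optn and 0.189 for Il1b. The lists called with the preset correlation, of which the globin list alone was called with an estimated one (adjusted p = 0.0115, the others 0.0977 to 0.345), had median interactions of -0.57 (globin chains), -0.15 (heme synthesis), -0.16 (red cell membrane), -0.13 (ribosome biogenesis), 0.11 (progenitor genes), 0.081 (oxidative stress) and 0.11 (lysosome).

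Other splits of the same libraries were counted. For comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real gene counts and the highest of the other splits were 6838 and 0 for E2 vs Ctrl, 426 and 1 for TMG vs Ctrl, 1055 and 1 for TMG_E2 vs E2, and 6841 and 0 for TMG_E2 vs TMG, so that 1 split of 10, the real one, gave a count as large in each. The list counts were 12 and 10, 7 and 8 (2 splits of 10 as large), 9 and 8, and 13 and 9. Among the 4 splits that part every same-numbered pair, the other 3 called 0 genes in each of the 4 comparisons, and up to 9 lists. For the interaction, 6 of 100 drawn splits gave 77 genes or more and 18 gave 7 lists or more (highest 12), but this count decides nothing for genes or lists. The 5 other splits at 77 genes or more, and 9 of those at 7 lists or more, kept the groups of a setting apart, so they carry the TMG effect and are no measure of chance. Of the 81 splits that mixed the groups in both settings, 8 gave 7 lists or more (highest 10), and each of these left a same-numbered pair together. The 10 that mixed the groups and parted every pair gave 6 lists or fewer, too few splits for a share under 0.05. The highest, 1611 genes, came from exchanging the TMG and Ctrl labels while keeping E2 and TMG_E2, which turns the difference of the TMG effects into their sum; the 225, 141, 108 and 90 genes of the other splits above 77 also kept the E2 and TMG_E2 libraries apart, so these counts point to that structure.

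The globin, heme and red cell membrane lists were called higher with TMG in uninduced cells and not in E2-treated cells, with adjusted p = 0.00351, 0.108 and 0.141 with an estimated correlation, so that the globin list alone kept its call. Of the globin genes, Hbb-bh1 lay near the level of 3 counts in a library without E2. Reads of E2-treated libraries in the TMG libraries would give each of the 32 members the same share of its E2 rise; relative to the Hbb-bs share of 0.0601%, the median member gained 20.4 times as much (quartiles 6.38 and 53.3), which argues against carry-over as the whole cause. Hbb-bs itself set that share, so the test cannot decide whether carry-over made the rise of Hbb-bs. An increment of fixed size, small beside the E2 level, stays open: the TMG effect in E2-treated cells differed from the one it gives by a median log2 of -0.0091 (SD 0.14) over the 32 members, but the same fold in both settings was missed by only -0.15 (SD 0.31). This test was first run on the 10 members called higher with TMG, where it came out in favour of the increment (0.042 against -0.30), and was then decided on all members because those 10 had been picked for their effect. A wider shift along the E2 change is a biological hypothesis that also stays open. A TMG library lay below the cut of 55%, which was chosen after the results had been seen. Of 669 other genes called and lowered 2-fold or more by E2 both without and with TMG, 64.3% lay lower with TMG (63.98%, 66.4% and 54.1% in the TMG libraries, where 55% was set for each), and 66.1% in E2-treated cells too. Of 624 so raised in both, 73.4% lay higher with TMG (71.3%, 70.2% and 70.2%), and 70.4% in E2-treated cells. Simulated groups with the E2 effect and no TMG effect, which share libraries in the same way, gave 49.6% (46.4% to 53.7%) and 50.1% (46.5% to 54.6%) without E2, though simulated genes vary independently and real ones do not. Over all genes kept, erythroid ones included, the TMG effect without E2 had a covariance of 0.0459 with the E2 effect from Ctrl. Simulated unchanged groups gave 0.0028 there. With the E2 effect measured in TMG-treated cells the covariance was 0.0371, and simulated unchanged groups gave -0.0029.

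The TMG_E2 libraries differed in their trend with transcript length (Spearman rho of the deviations 0.39 in replicate 1 and -0.58 in replicate 3) and GC content (-0.53 and 0.35). With that trend removed and the replicate number as a block, 98.5% of the 1055 calls between TMG_E2 and E2 were kept (95.8% without the block), which argues against it as the whole cause. Without any 1 TMG_E2 library at least 72.9% were kept, which argues against a single library that stands apart. With the replicate block alone, all 1055 calls were kept, among 1454 genes called. A biological effect of TMG remains a hypothesis, found and tested on the same data, and no batch other than the replicate number was tested.

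Lars2 and AK155692 were lower with TMG than in Ctrl, where Ctrl replicate 2 was far higher than the others. Without that library the adjusted p-values were 0.0262 (log2 -0.48 ± 0.10) and 0.00403 (-0.80 ± 0.13), which argues against it as the whole cause, though the folds shrank from -1.08 and -1.48. The Lars2 call ended without TMG replicate 1 (adjusted p = 0.0596), 2 (0.0939) or 3 (0.0741), and with DESeq2 (0.0561). Why Ctrl libraries vary in these genes was not tested.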

How the results depend on the processing

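The length and GC correction was chosen after seeing the data; the other alternatives were planned. For TMG vs Ctrl the gene count of 426 became 675 with the replicate block, 768 with only the groups compared, 786 with the length and GC offset and 1130 with both offset and block. For TMG_E2 vs E2 the count of 1055 became 539 with only the groups compared and 2022 with offset and block. For the interaction the count of 77 became 48 with filterByExpr, 178 with no filter, 171 with the block, 40 with limma-voom, 185 with the offset and 365 with offset and block. With only the groups compared, TMG vs Ctrl had more calls than TMG_E2 vs E2, the reverse of the main fit, which shares the spread over all groups. Which setting had more called genes thus depended on the fit. TMG_E2 replicates differed more (chi-square per degree of freedom 8.66 to 13.1) than replicates of the other groups (2.41 to 4.17). Whether this moved the counts was not tested, nor were other causes. The E2 comparisons kept their gene counts within 1.5 times under every alternative run. Lists called with an estimated correlation were 4, 1, 0, 4 and 1 (main 12, 7, 9, 13 and 7), and fry called 20, 9, 11, 21 and 3. With fry the cholesterol list lost its call in TMG vs Ctrl (0.0606), as did the progenitor (0.133), ribosome biogenesis (0.1497), oxidative stress (0.0968) and lysosome (0.128) lists in the interaction.

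Left-out libraries gave 6549 to 6620 genes for E2 vs Ctrl, 196 to 257 for TMG vs Ctrl, 656 to 1160 for TMG_E2 vs E2, 6660 to 6822 for TMG_E2 vs TMG and 18 to 161 for the interaction. They gave 12 to 14, 6 to 8, 8 to 10, 13 to 14 and 6 to 9 lists. The correlation of TMG effects was 0.282 to 0.489 (0.225 with filterByExpr), that of E2 effects 0.982 to 0.989 (0.954), and that of the TMG effect with the E2 effect 0.142 to 0.234 (0.0687) or, measured from TMG, 0.234 to 0.338.

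In TMG_E2 vs E2, Gata1 and Klf1, not called under any alternative (adjusted p 0.541 to 0.978 and 0.390 to 0.989), changed sign: Gata1 was at -0.0070 with library size alone and -0.0099 without TMG_E2 replicate 2 (left-out range -0.0099 to 0.042), and Klf1 at 0.035 without TMG_E2 replicate 1 (range -0.070 to 0.035). The E2 comparisons kept all named calls in 782 and 255 tries; calls of 10, 18 and 15 named genes ended at least once in TMG vs Ctrl, TMG_E2 vs E2 and the interaction (50 of 712, 63 of 969 and 138 of 572 tries). Ift52, not called under any alternative (adjusted p 0.661 to 1), changed sign in TMG_E2 vs E2: from -0.0016 to 0.0023 with filterByExpr, 0.00060 with no filter, 0.0086 with RLE size factors, 0.0086 with DESeq2, 0.010 without TMG_E2 replicate 1, 0.042 without E2 replicate 2 and 0.0015 without TMG_E2 replicate 3 (left-out range -0.030 to 0.042). For TMG vs Ctrl same-numbered libraries correlated at 0.0876, 0.0295 and 0.188, not all over 0.1, so by this check they share only a number, though each correlated best with its own and the other comparisons link the same numbers. The replicate block gave 9 lists there, with progenitor genes (0.0138) and mast cell markers (lower, 0.0184) added, and called Gata1 (0.0480) and Klf1 (0.0379). The length and GC offset with replicate block also called Ogt (0.0188) and Gata2 (0.0422) there and Klf1 in the interaction (0.0239, and 0.0442 with the offset alone). In the interaction the replicate block alone, without the offset, gave 9 lists, with cholesterol and autophagy added, and called Gata2. In E2 vs Ctrl, TMG_E2 vs E2 and TMG_E2 vs TMG, where numbers pair, the replicate block alone changed the calls of Ogt, Ift20 and iron handling and of no other named gene or list. At this depth 1.2-fold changes are recovered only in part.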

Other observations

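The genes in this part were picked after their values were seen, except Aox4, Oga, Fndc5, Pcx and the family members named by rule. Several genes moved the same way with TMG in both settings. Besides Aox4, Oga and Fndc5, Acad10, an acyl-CoA dehydrogenase gene, fell by 0.57 ± 0.07 on the log2 scale without E2 (edgeR adjusted p = 0.000103) and by 0.67 ± 0.06 with E2 (adjusted p = 9.54e-06). Slc25a4, the ADP/ATP carrier of mitochondria, was at log2 -0.32 ± 0.05 and -0.68 ± 0.06, and Pcx, pyruvate carboxylase, at -1.09 ± 0.15 and -0.55 ± 0.08, all called in both settings.

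Intraflagellar transport genes, which serve the building of cilia, were grouped only after their values were seen; they are none of the fixed lists, and no test of the group was run, so the counts are a description. Of 9 tested, 6 were called lower with TMG in E2-treated cells (median log2 -0.32), against 591 of all 8273 genes, and 2 without E2 (median -0.06). Ift172 went from 39.0 to 23.2 CPM with E2 (log2 -0.74 ± 0.07, adjusted p = 9.54e-06) and from 24.7 to 17.9 CPM without it (-0.46 ± 0.07, adjusted p = 0.00124). Ift140 went from 22.6 to 13.7 CPM with E2 (-0.71 ± 0.07, adjusted p = 2.21e-05), and fell by 0.30 on the log2 scale without it, a call that ended without 4 of the 6 libraries (adjusted p up to 0.0735). The calls of Ift27 (log2 -0.32), Ift46 (-0.41), Ift57 (-0.25) and Ift81 (-0.74) with E2 each ended without at least 1 library, with adjusted p-values up to 0.0802, 0.225, 0.0908 and 0.0833. With only the groups compared those of Ift46 (0.134), Ift57 (0.0588) and Ift81 (0.0675) ended too, and that of Ift46 also with filterByExpr (0.0607), RLE size factors (0.0510) and DESeq2 (0.0565), so Ift172 and Ift140 alone kept theirs. Ift52 (log2 -0.0016 ± 0.05, adjusted p = 0.990) and Ift20 (0.17 ± 0.06, adjusted p = 0.0587) were not called with E2; Ift20, the member that lay highest, passed with no filter (0.0384), RLE size factors (0.0450), the replicate block (0.0202) and the length and GC offset (0.0282), and without TMG_E2 replicate 1 (0.0273) or E2 replicate 2 (0.0338). The difference between the settings was not called for any of the 9 (lowest edgeR adjusted p = 0.0572, Ift140).

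A family of near-identical genes (BB287469, Gm2016, Gm2022, Gm5039, Gm5662 and Gm8300), whose transcripts share 33.0% to 92.4% of their 31-base words with another member, rose with E2 and with TMG alone. The summed level of the family was 21.2 ± 1.21 CPM in Ctrl, 49.5 ± 2.42 with TMG, 481 ± 42.3 with E2 and 539 ± 72.7 with both (n = 3 each). As 1 feature the sum was 2.34-fold higher with TMG than in Ctrl and 22.7-fold higher with E2, each with a two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows, and 1.12-fold higher with TMG_E2 than with E2 (exact p = 0.3). Reads that match several members are divided among them, so the values of single members are uncertain.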
